A study of Mus musculus with 11 samples.

How the data were processed

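The deposited files hold 11 single-colour Agilent mouse expression arrays, hybridised with Cy3-labelled RNA from tissues of E12.5, the day of gestation given by the labels. There were 3 arrays of the visceral yolk sac (VYS), 3 of the parietal yolk sac (PYS, the endodermal cells with Reichert's membrane), 2 of placenta, 2 of liver and 1 of small intestine. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

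The values analysed were the processed signal of each spot, an intensity on a linear scale, which per the file headers was made by Agilent Feature Extraction 10.7.3.1 with the protocol GE1_107_Sep09. The submitters' processing notes name version 9.5 of the same software. This deposited signal was already background-subtracted and detrended within each array and had not been scaled between arrays. The deposited series table holds the same intensity on a linear scale: on each array at least 99.3% of its values equalled the processed signal, summarised per probe, within 0.1%. Its scale, centring and direction were therefore known. Its column medians were 29.6, 26.8 and 24.5 for VYS replicates 1 to 3, and 23.1, 23.2 and 16.5 for PYS replicates 1 to 3. They were 30.4 and 31.4 for the placenta, 26.6 and 32.8 for the liver and 37.7 for the small intestine. No deposited column went unused.

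Control spots and spots that the scanner software marked as non-uniform or as population outliers were left out (117 to 347 of 59305 spots per array), and spots of one probe were averaged, which gave 55681 probes. Between 45.8% and 60.5% of the probes were well above background per array, and no probe was saturated. The 75th percentile of the signal was 140 to 185 on the PYS arrays and 329 to 555 on the others, so the PYS arrays were dimmer. The log2 signal minus each array's own 75th percentile was used throughout, and every log2 level is relative to that point. The number of arrays limits the precision.

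The files give an accession per probe and no gene symbol. Accessions were matched without versions to a RefSeq gene table of assembly GRCm38.p6, which named 27656 of the 55681 probes (49.7%), among them 98.7% of the 26640 probes with a RefSeq mRNA accession. The array grid was built on mm9, another assembly, so no coordinates are given. The 28025 unnamed probes entered the tests under their own accession, 16194 of them as chromosome intervals, and counts of genes below include them unless the text says named. For a gene with several probes the one with the highest mean over all 11 arrays was used. The 27053 features well above background on at least 2 of the 11 arrays were tested, of which 16762 were named and 15623 were above background on every array.

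All tests came from one limma fit (lmFit and eBayes, limma 3.58.1 in R 4.3.3) with one mean per tissue and no covariate, 6 residual degrees of freedom and a prior worth 2.09. The single small intestine array was assumed to vary like the others. P-values were adjusted by the Benjamini-Hochberg method over all features of a contrast, and every adjusted p printed for a gene is limma's. A gene was called at an adjusted p under 0.05 with a fold of at least 2. A gene was counted as enriched in a tissue when every contrast with the other tissues had an adjusted p under 0.05 and a fold of at least 4, and when it was above background on all arrays of that tissue. A gene with no probe above background on any array of the lower tissue has only a bound, written as at least N-fold. The bound sets the higher tissue's mean against the mean, over the lower tissue's arrays, of the higher of the probe's own value and the array's lowest value among probes well above background. The small intestine bound rests on 1 array.

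The design was fixed before the data were examined, with 24 gene lists from textbook knowledge and the rule for the genes named. For VYS against PYS the rule took, in each direction, the 8 called genes of largest fold that were above background on all 6 arrays, and the 6 of smallest p that were not above background in the lower tissue. It took 14 genes each for the VYS-enriched and PYS-enriched sets and 5 each for the other sets, ordered by the largest of their p-values. It took 3 genes per direction for each other contrast with placenta, liver or small intestine, among those above background on all arrays of both tissues. For each list it took the 3 called members of largest fold and the largest called member in the opposite direction. It also took 8 label checks (Afp, Ttr, Lama1, Sparc, Tpbpa, Prl3b1, Alb and Cdx2). Only names that are gene symbols qualified, so accession, clone and numbered placeholder names were passed over.

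Gene lists were tested in VYS against PYS with limma's camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over the 24 lists), with an estimated correlation and fry beside it. Camera compares a list's genes with all other genes, while fry tests only whether a list's genes moved one way on balance. Lists were tested in the enriched sets with one-sided Fisher's exact tests, adjusted over the 24 lists of each set. Their background was the named genes above background on all arrays of the tissue.

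The same code was tested on simulated arrays with 26942 genes. In VYS against PYS it recovered 14.9%, 77.6% and 84.8% of genes changed 2-fold, 4-fold and 8-fold, with 7 false calls. The enriched rule recovered 0, 10.4% and 62.1% of genes raised 2-fold, 4-fold and 8-fold, with 0 false calls. A change exactly at the fold threshold, 2-fold for calls and 4-fold for the enriched rule, is often estimated under it, which lowers recovery there by construction. The median estimate of the genes changed 2-fold was a log2 of 0.96, and a failure to reach the adjusted p may also have lowered their recovery. Only 200 genes were changed, far fewer than were called in the real contrast, so these rates do not carry over to it. Over 20 draws with no change 0 lists were called, and a list raised 2-fold was called in 20 of 20 draws. The genes were simulated as independent of each other, so these draws cannot show how often camera calls lists of correlated genes.

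The alternatives tried were normexp background correction (offset 50), quantile scaling, scaling to the median of probes above background on all arrays, 3 other filters on dim probes and the series table in place of the scanner signal. Slide was tried as a fixed block, as a random block and within each slide. The replicate number was tried as a block. Further fits took only the tissues compared, left out the small intestine, left out each replicate in turn, averaged a gene's probes, or used a trended robust prior. Other fold thresholds, estimated correlations and fry completed the planned set. Because the files carry no mean signal column, normexp used the median signal with the median background. A common floor for all arrays and a rule that the higher tissue be above background on all its arrays were added after seeing the data. Slide 1 held all VYS arrays, PYS replicate 1, liver replicate 1 and the small intestine, slide 2 held PYS replicates 2 and 3 and both placenta arrays, and slide 3 held liver replicate 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.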

Results

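Messenger RNA levels were measured in 5 tissues of the mouse conceptus at E12.5, the day of gestation given by the labels. The VYS (n = 3) is a membrane around the embryo with an absorptive endoderm, a mesoderm layer and blood vessels. The PYS (n = 3) lines the trophoblast and lays down Reichert's membrane, a thick basement membrane. Placenta (n = 2), liver (n = 2) and small intestine (n = 1) served as comparison organs. Between 25485 and 33660 of 55681 probes were well above background per array. The series title names markers of yolk sac cells, so the comparisons ask which genes set each yolk sac apart from the other and from the comparison organs.

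Known markers were looked up first, as a check of the labels. Afp (NM_007423), the fetal albumin-like plasma protein, stood at log2 9.84 ± 0.047 in the VYS (SD, n = 3) and 9.66 ± 0.080 in the liver (SD, n = 2), a difference that did not pass the test (adjusted p = 0.797). It was 50.0-fold higher in the VYS than in the PYS. Ttr (NM_013697), a thyroid hormone carrier, was 55.1-fold higher in the VYS than in the PYS and 7.07-fold higher than in the liver. Lama1 (NM_008480), a laminin chain, reached 10.07 ± 0.26 in the PYS (SD, n = 3), 11.97-fold above the VYS. Sparc (NM_009242), a matrix protein of Reichert's membrane, was 2.21-fold higher in the PYS than in the VYS. Tpbpa (NM_009411), a spongiotrophoblast marker, was above background in the placenta and on 0 of 3 PYS arrays, at least 57.1-fold higher in the placenta. Prl3b1 (NM_008865), a placental lactogen, was also on all PYS arrays, at 6.33 ± 0.57 against 9.31 ± 0.024 in the placenta, a difference of 7.93-fold (adjusted p = 8.41e-05). Alb (NM_009654), serum albumin, was 10.3-fold higher in the liver than in the VYS. Cdx2 (NM_007673), an intestinal and trophoblast transcription factor, was at 1.92 in the small intestine and 2.17 ± 0.33 in the placenta, which did not differ by the test (adjusted p = 0.771).

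**Figure D1:**
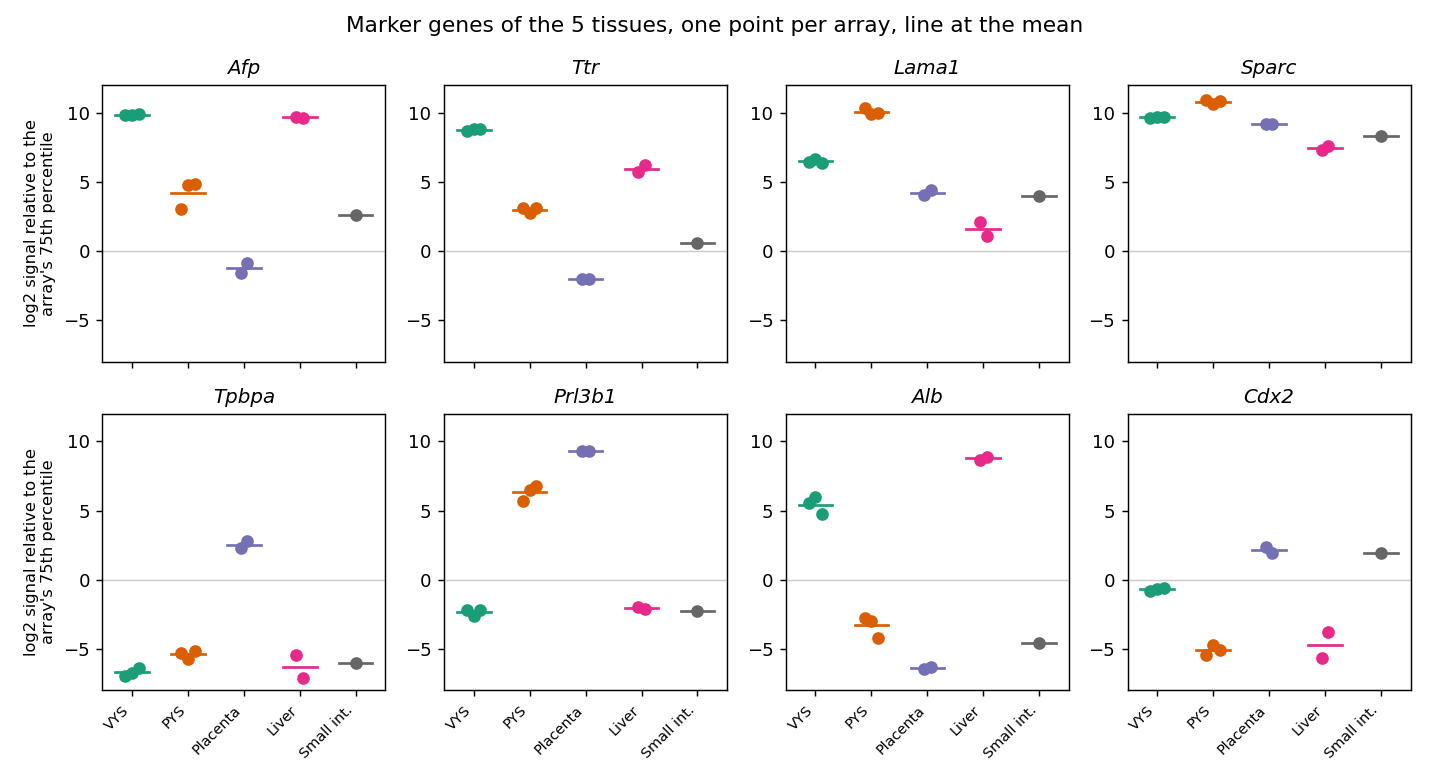
Levels of 8 marker genes in every sample, with the log2 signal relative to the array's 75th percentile on the vertical axis, a point per array and a line at the tissue mean. Afp stood near 9.84 in the VYS and 9.66 in the liver, Lama1 at 10.07 in the PYS, and Prl3b1 at 6.33 in the PYS against 9.31 in the placenta.

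Arrays of one tissue correlated at r = 0.961 to 0.992 across the tested features, and arrays of different tissues at 0.786 to 0.907. Genes are not independent replicates, so these r values only describe likeness. Over the features above background on every array, the spread between replicate arrays, the SD of the log2 differences of a pair divided by the square root of 2, was 0.145 to 0.206 for VYS pairs, 0.292 to 0.387 for PYS pairs, 0.207 for the placenta and 0.421 for the liver. The first 2 principal components held 41.5% and 25.8% of the variance. The PYS arrays stood apart from the other tissues on the first component, and the placenta on the second.

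**Figure D2:**
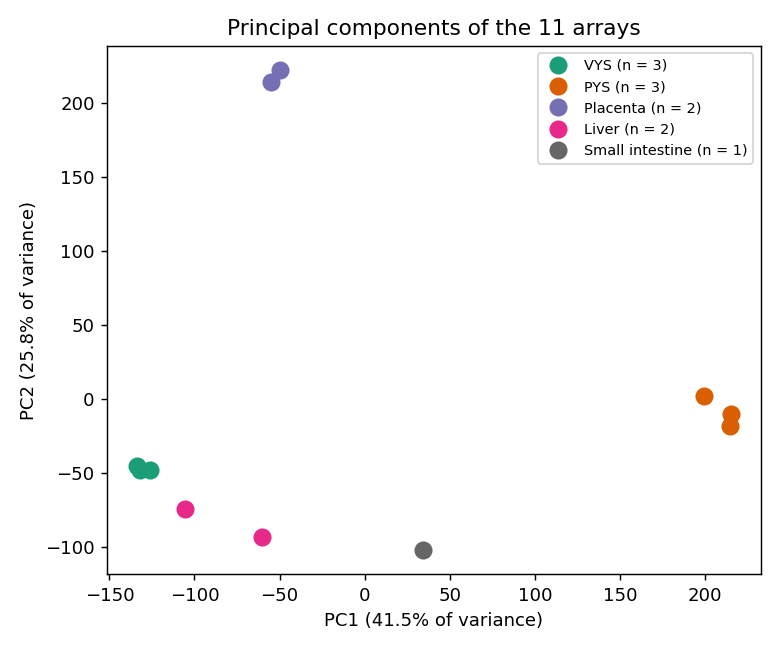
The 11 arrays on the first 2 principal components of the tested features, a point per array coloured by tissue, with each axis labelled by its share of the variance (41.5% and 25.8%). The 3 PYS arrays lie to the right of all others on the first component and the 2 placenta arrays above all others on the second.

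The main comparison set the VYS against the PYS, the pair of extraembryonic endoderm tissues. The genes furthest above the PYS in the VYS included the fibrinogen chains Fgg (NM_133862) and Fgb, 1149.9-fold and 832-fold higher. The apolipoproteins Apom, Apoa1 and Apob were 771-fold, 729-fold and 441-fold higher. Lum, a collagen-binding proteoglycan, Maob, a monoamine oxidase, and Aldob, an aldolase of liver and kidney, were 588-fold, 391-fold and 387-fold higher. The log2 differences of these 8 genes had an SE of 0.13 to 0.60, and the largest adjusted p was 5.01e-06. Of the genes not above background on any PYS array, Vtn, the plasma adhesion protein vitronectin, was at least 299.6-fold higher in the VYS, and Itih2, which encodes a serum hyaluronan-binding chain, at least 92.7-fold. Akr1c19, an aldo-keto reductase, Gys2, the liver glycogen synthase, Abcc2, an organic anion pump, and Frem1, a basement membrane protein, were higher by at least 86.0-fold, at least 83.0-fold, at least 61.9-fold and at least 45.8-fold, respectively.

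Gkn2, a gastrokine, was 2541-fold higher in the PYS than in the VYS, Pi16, a peptidase inhibitor family member, 1804-fold, and Pga5, a pepsinogen, 745-fold. Fst, the activin antagonist follistatin, Edn2, an endothelin, and Bmper, a BMP-binding protein, were 1096-fold, 608-fold and 485-fold higher. Prl2c5 and Prl8a2, members of the prolactin family of trophoblast and decidua, were 2378-fold and 798-fold higher. Near-identical copies of prolactin-family genes can share a probe, so which member was measured is uncertain. The SE of these 8 log2 differences was 0.19 to 0.67, with adjusted p of at most 9.48e-06. Of genes not above background on any VYS array, Prl2b1 was at least 419.8-fold higher in the PYS and Birc7, an inhibitor of apoptosis, at least 378-fold. Arsi, a sulfatase, Npas3, a transcription factor, Mme, the peptidase neprilysin, and Kcnq5, a potassium channel, were higher by at least 209.9-fold, at least 133-fold, at least 74.8-fold and at least 16.1-fold.

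By limma's test, 4494 of 27053 genes were higher in the VYS and 7477 in the PYS, so 37.5% of calls were higher in the VYS. Named features alone gave 3519 and 3823, a far smaller excess. In 507 of the calls higher in the PYS neither tissue was above background on any array, and 5409 had the PYS above background on all its arrays, against 4429 of the calls higher in the VYS. Quantile scaling moved the split to 5913 and 5569 genes (51.5% higher in the VYS) and the median log2 difference of all genes from -0.23 to 0.067. With slide as a block, where the contrast rests on PYS replicate 1, the counts were 4501 and 7090. Within slide 1, which holds 1 PYS array, the median log2 difference of all genes was -0.23. Among the 15623 genes above background on all arrays the median log2 difference was -0.0088.

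Plasma proteins made by endoderm and liver were higher in the VYS as a group. Of 29 measured members 26 were higher and 1 lower, 26 and 1 also when adjusted over the list alone. The median log2 difference was 7.28, or 6.94 with members below background at their bound (camera adjusted p = 1.53e-11). Fgg and Vtn led, with Serpinf2, the plasmin inhibitor, 853-fold higher. The exception F10, coagulation factor X, was 30.9-fold higher in the PYS, and its other probe went the opposite way. Lipoprotein genes behaved alike, with 24 of 27 higher and 0 lower under both adjustments, a median of 5.07, or 3.79 with bounds (camera adjusted p = 3.33e-10). Apoa4, an intestinal apolipoprotein, was 857-fold higher, above background on 2 of 3 PYS arrays. Genes of the hepatoblast and hepatocyte followed with 18 of 27 higher and 7 lower under both adjustments, a median of 3.39, or 1.73 with bounds (camera adjusted p = 0.00267; adjusted p = 0.0595 with an estimated correlation). Dlk1, a Notch-family surface protein, was 256-fold higher in the VYS, and Cyp3a11, a cytochrome P450, was at least 4.22-fold higher in the PYS, where 2 of 3 arrays measured it.

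Lists of absorptive functions were not all called by camera, and they were not tested against each other. Of 30 brush border and nutrient transport genes 23 were higher in the VYS and 1 lower, 24 and 1 adjusted over the list alone, with a median of 3.55, or 2.45 with bounds (camera adjusted p = 3.75e-07). The glucose transporter Slc2a2, the zinc transporter Slc39a5 and the amino acid transporter subunit Slc7a9 were at least 85.0-fold, at least 124-fold and 173-fold higher. Mep1a, a meprin subunit and the member called lower, was above background in neither tissue. Endocytic receptors and lysosomal genes were not called by camera, with 12 of 30 higher and 4 lower under both adjustments and a median of 0.20 (camera adjusted p = 0.348; fry adjusted p = 3.76e-05 toward the VYS). The 3 called members of largest fold were Fcgrt, the neonatal Fc receptor, 212-fold, Lrp2, the receptor megalin, 109.6-fold, and Amn, the partner of cubilin, 66.6-fold higher in the VYS. Lrpap1, a chaperone of such receptors, was 3.96-fold higher in the PYS. Iron and heme genes were higher in the VYS in 11 of 21 and lower in 1 under both adjustments, with a median of 1.23 (camera adjusted p = 7.82e-05). Trf, transferrin, and Hpx, the heme carrier hemopexin, were 156-fold and 146-fold higher, Hpx being above background on 1 of 3 PYS arrays. Heph, an iron oxidase, was at least 80.5-fold higher, with 1 of its 2 probes the opposite way. Hamp, the member called lower, was above background in neither tissue.

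Cholesterol synthesis genes were higher in the VYS in 22 of 25 and lower in 1 under both adjustments, with a median of 3.07 (camera adjusted p = 2.3e-08; adjusted p = 0.218 with an estimated correlation). Dhcr24 and Tm7sf2, reductases of the pathway, were 40.6-fold and 33.1-fold higher, and Pcsk9, which lowers the LDL receptor, at least 106-fold. Insig1, which restrains the pathway, was 2.43-fold higher in the PYS. Of 34 imprinted genes 23 were higher in the VYS and 1 lower under both adjustments, with a median of 2.18, or 1.97 with bounds (camera adjusted p = 1.42e-06; adjusted p = 0.0847 with an estimated correlation). Nnat, neuronatin, and Slc22a2, an organic cation transporter, were at least 435-fold and at least 83.1-fold higher, and Ano1, a chloride channel, was 3.26-fold higher in the PYS. Cell cycle genes were higher in the VYS in 7 of 25 and lower in 0 under both adjustments, with a median of 0.88 (camera adjusted p = 0.000293; adjusted p = 0.407 with an estimated correlation). Ccne1, Bub1b and Cdk1 were 9.56-fold, 3.18-fold and 2.90-fold higher. Steroid hormone synthesis was not called by camera, with 6 of 14 higher, 6 lower under both adjustments and a median of 0.49 (camera adjusted p = 0.673; fry adjusted p = 0.000133 toward the VYS). Hsd3b1 and Hsd11b2, hydroxysteroid dehydrogenases, were higher in the VYS by at least 146-fold and at least 18.8-fold, and Sult1e1, the estrogen sulfotransferase, higher in the PYS by at least 4.39-fold, measured on 2 of 3 PYS arrays.

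Mesenchyme and fibrillar collagen genes were higher in 20 of 27 and lower in 4 under both adjustments, with a median of 4.66, or 3.53 with bounds (camera adjusted p = 7.59e-05; adjusted p = 0.288 with an estimated correlation). Col6a3 and Postn, matrix proteins, were 408-fold and 249-fold higher, each above background on 1 of 3 PYS arrays. Mfap5, a microfibril protein, was 30.2-fold higher in the PYS. Erythroid genes were higher in 22 of 26 and lower in 1 under both adjustments, with a median of 3.25, or 2.46 with bounds (camera adjusted p = 9.18e-07; adjusted p = 0.278 with an estimated correlation). The embryonic globin Hba-x was 25.2-fold higher, the blood group protein Kel at least 24.2-fold and Trim10 at least 7.81-fold. For Ermap, called 2.03-fold higher in the PYS, 2 of 3 probes went the opposite way. Endothelial genes were higher in 17 of 26 and lower in 4 under both adjustments, with a median of 2.67 (camera adjusted p = 0.00161; adjusted p = 0.354 with an estimated correlation). Lyve1, on 1 of 3 PYS arrays, Stab2, and Plvap, on 2 of 3, were 106.6-fold, 56.0-fold and 50.3-fold higher, and Tek, the angiopoietin receptor, was 5.51-fold higher in the PYS.

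The lists of mesothelium, of leukocytes and of intestinal muscle and enteric neurons were not called by camera. Mesothelial genes split 6 higher and 6 lower of 17 under both adjustments, with a median of -0.22, or 0 with bounds (camera adjusted p = 0.997, toward the PYS, while fry pointed to the VYS). Msln, mesothelin, was 515-fold higher in the PYS, against 1 of 3 VYS arrays above background, while Bnc1 and Rspo1 were at least 10.5-fold and at least 26.4-fold higher in the VYS. Macrophage and leukocyte genes split 10 higher and 8 lower of 23 under both adjustments, with a median of 0.42, a mean of -0.049 and a test in the direction of the VYS (camera adjusted p = 0.673; fry adjusted p = 0.0384). The mannose receptor Mrc1 was 69.4-fold higher in the VYS and the chemokines Ccl4 and Ccl3 at least 56.5-fold and 23.3-fold higher in the PYS. Intestinal muscle and enteric neuron genes split 9 higher and 5 lower of 25 under both adjustments, with a median of 0.27, or 0 with bounds (camera adjusted p = 0.533). The smooth muscle actins Actg2 and Acta2 were 47.4-fold and 42.0-fold higher in the VYS and the neuronal tubulin Tubb3 25.4-fold higher in the PYS.

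On the side of the PYS, 17 of 21 parietal endoderm markers were higher and 2 lower under both adjustments, with a median log2 difference of -3.58 for VYS minus PYS (camera adjusted p = 1.95e-06; adjusted p = 0.181 with an estimated correlation). Fst led, Stra6, a retinol-binding protein receptor, was 879-fold higher in the PYS, and Snai2, a transcription factor, was at least 38.1-fold higher in the VYS. Collagen folding genes were higher in the PYS in 18 of 27 and lower in 4, or 18 and 5 adjusted over the list alone, with a median of -1.87 (camera adjusted p = 0.000271; adjusted p = 0.354 with an estimated correlation). P4ha1 and Plod3, a prolyl and a lysyl hydroxylase of collagen, were 29.7-fold and 17.9-fold higher in the PYS, and Loxl1, a cross-linking enzyme, was at least 106-fold higher in the VYS. ER chaperones and unfolded protein response genes were higher in the PYS in 10 of 30 and lower in 0 under both adjustments, with a median of -0.75 (camera adjusted p = 4.73e-05; adjusted p = 0.354 with an estimated correlation). Creb3l1 and Creb3l2, transcription factors of the secretory pathway, and Pdia3, a disulfide isomerase, were 18.0-fold, 4.10-fold and 4.47-fold higher.

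Basement membrane genes went both ways, 13 of 31 higher in the VYS and 14 in the PYS, or 13 and 15 adjusted over the list alone, with a median of -0.92, a mean of 0.21 and a test in the direction of the PYS (camera adjusted p = 0.673). Frem1 and Col4a5, a minor collagen IV chain, were higher in the VYS by at least 45.8-fold and at least 40.2-fold, whereas the major chains Col4a1 and Col4a2 were 30.3-fold and 33.2-fold higher in the PYS. Endoderm transcription factors also split, 14 of 26 higher in the VYS and 8 in the PYS under both adjustments, with a median of 1.44, or 0.83 with bounds (camera adjusted p = 0.161; fry adjusted p = 6.83e-06 toward the VYS). Nr1h4, the bile acid receptor, Foxa1 and Hnf1a were higher in the VYS by at least 84.8-fold, at least 51.6-fold and at least 92.7-fold, and Sox17 was 66.6-fold higher in the PYS. Immediate early and heat shock genes were higher in the PYS in 12 of 24 and in the VYS in 0 under both adjustments, with a median of -1.04 (camera adjusted p = 0.0142; adjusted p = 0.217 with an estimated correlation). Klf4, Nr4a1 and Atf3, transcription factors induced by stress and by tissue handling, were 32.6-fold, 18.9-fold and 8.92-fold higher, and within slide 1 the list missed the threshold (camera adjusted p = 0.071).

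Trophoblast genes were higher in the PYS in 29 of 37 and in the VYS in 2, or 30 and 2 adjusted over the list alone, with a median of -4.48, or -2.94 with bounds (camera adjusted p = 4.38e-08; adjusted p = 0.181 with an estimated correlation). In 7 of the 29 neither tissue was above background. Prl2a1, Prl7a1 and Prl7d1, prolactin-family hormones, were higher in the PYS by at least 1303-fold, at least 1202-fold and at least 337-fold, and Hand1, a transcription factor of trophoblast giant cells and of mesoderm, was 8.50-fold higher in the VYS. Decidua and uterus genes were higher in the PYS in 16 of 24, 3 of them with neither tissue above background, and in the VYS in 6 under both adjustments, with a median of -1.71, or -1.20 with bounds (camera adjusted p = 0.0172; adjusted p = 0.217 with an estimated correlation). The granzymes Gzme and Gzmg of uterine natural killer cells were 489-fold and at least 118-fold higher in the PYS, and Hand2, a stromal transcription factor, was 25.4-fold higher in the VYS. With a common floor for all arrays, chosen after seeing the data, the decidua list missed the threshold (camera adjusted p = 0.119).

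Of the 24 lists, 17 were called by camera, and 4 held with an estimated correlation, namely plasma proteins, lipoproteins and brush border (adjusted p = 0.00803 each) and iron and heme (adjusted p = 0.0239). By fry 21 lists moved one way on balance. When VYS and PYS arrays were regrouped in the 9 other splits of these 6 arrays, camera with the preset correlation still called 11 to 15 lists. Those splits keep part of the tissue difference, so they cannot show how many lists it would call without one. Lists that lost their call with an estimated correlation have only weak support from camera. With slide as a block the means equalled those of slide 1 alone, which holds 1 PYS array. These mean log2 differences were 6.34 for plasma proteins, 5.01 for lipoproteins, 3.36 for brush border, 3.68 for mesenchyme, 3.15 for erythroid, 2.75 for endothelium, 2.55 for hepatocyte and 2.44 for iron and heme genes. They were 3.20 for cholesterol synthesis, 2.77 for imprinted, 1.10 for cell cycle, -3.09 for parietal endoderm, -0.93 for collagen folding, -0.89 for ER chaperone, -4.54 for trophoblast, -1.99 for decidua and -1.03 for immediate early genes.

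**Figure D3:**
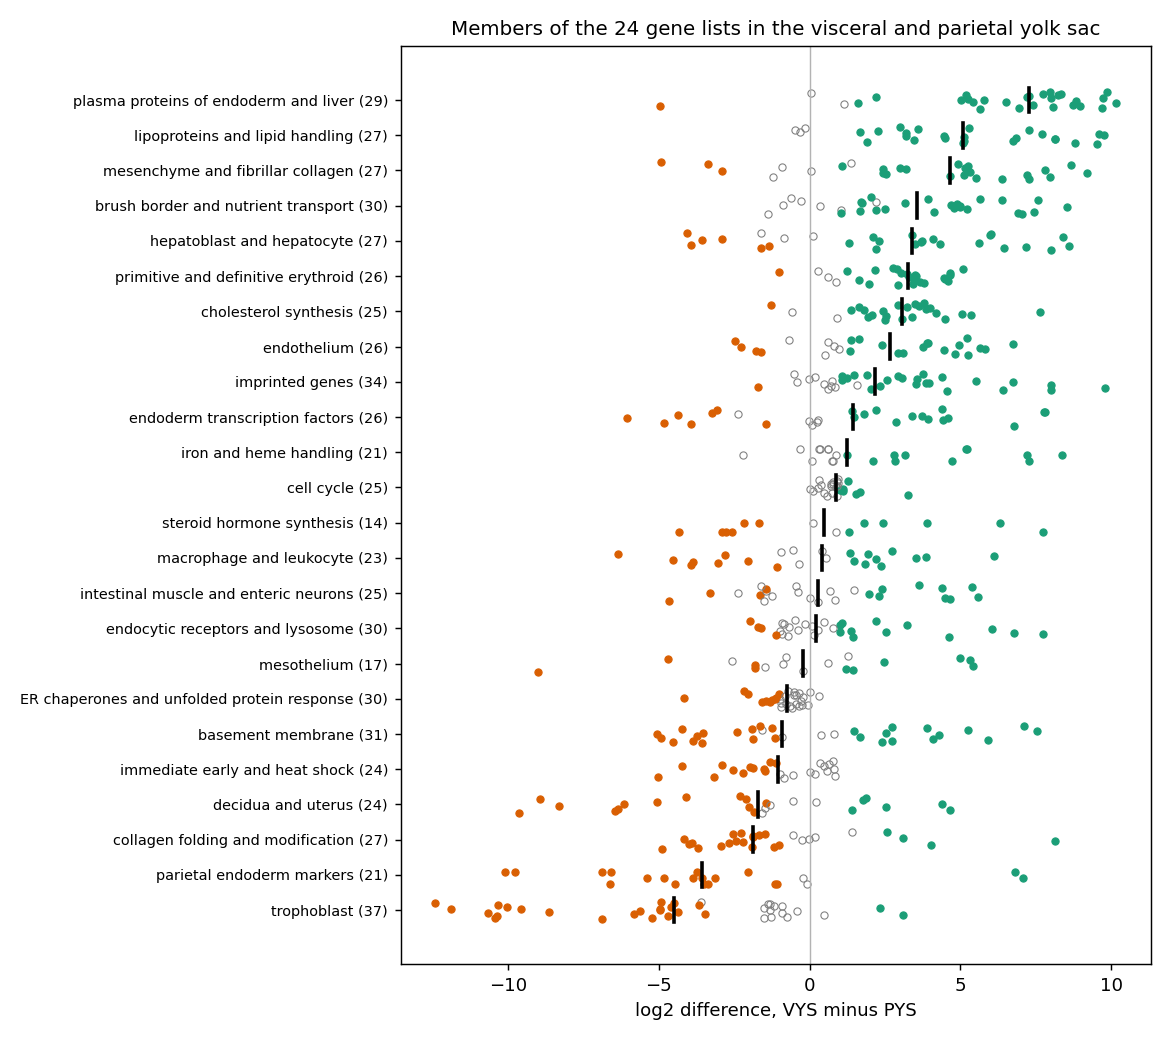
Log2 difference between VYS and PYS (horizontal axis, positive values higher in the VYS) of each measured member of the 24 gene lists (vertical axis, with the number of members), with a black bar at the fitted median, green and orange points for members called higher in the VYS and the PYS, and open grey points for members not called or above background in neither tissue. The medians run from 7.28 for plasma proteins to -4.48 for trophoblast genes.

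Enriched genes were sought next, those higher in one tissue than in each of the other 4. In the VYS 382 genes were enriched, 326 of them named. Fxyd2, a sodium pump subunit, was 163-fold above the PYS and 332-fold above the liver. Slc13a3, a dicarboxylate transporter, was 19.4-fold above the PYS, Slc23a3 21.3-fold, and Slc7a9 36.2-fold above the liver. Fmo1, a flavin monooxygenase, was 40.5-fold above the placenta, and Entpd2, an ectonucleotidase, 46.3-fold. Apoa4 was not above background in placenta, liver or small intestine, and at least 1710.2-fold above the liver. Eps8l3 was at least 361-fold above the PYS, and Muc13, a membrane mucin, 21.0-fold above the liver. Fgf1, a growth factor, and Sigirr, an interleukin receptor relative, were 43.3-fold and 7.28-fold above the liver. Glyat, a glycine acyltransferase, Flacc1 and Mfsd4b5 were above background in no other tissue and at least 11.5-fold, at least 14.2-fold and at least 10.3-fold above the PYS. The largest adjusted p of these 14 genes over the 4 contrasts was 7.44e-06.

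Of the 29 brush border genes above background in the VYS 8 were enriched there, among them Pdzk1, Slc39a4, Vil1 and Slc3a1 (Fisher adjusted p = 5.42e-06). So were 7 of 26 lipoprotein genes (adjusted p = 1.90e-05), among them Apoc3 and Mttp, 5 of 30 endocytic genes (adjusted p = 0.00473), namely Amn, Lrp2, Cubn, Fcgrt and Ctsc, 4 of 24 mesenchyme genes (adjusted p = 0.0128), namely Col5a1, Lum, Col1a2 and Col1a1, and 4 of 29 plasma protein genes (adjusted p = 0.0209), namely Ttr, Kng1, Fga and Fgg. The other 19 lists did not pass. Genes listed here by set were taken from the lists and not by the rule for named genes.

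In the PYS 677 genes were enriched, 419 of them named. The collagen IV chains Col4a1 and Col4a2, which form the network of basement membranes, were 25.8-fold and 24.2-fold above the placenta. Itga6, a laminin receptor subunit, was 11.5-fold above the VYS, and Ntn4, a laminin-related protein, 97.2-fold above the placenta. Pi16 was 255-fold above the placenta, Scgb3a1, a secretoglobin, 69.0-fold above the VYS and Wfdc1, a secreted inhibitor family member, 18.4-fold. Gdf9, a TGF-beta family factor known from oocytes, was 92.5-fold above the placenta, and Lpar3, a lysophosphatidic acid receptor, 41.4-fold. Sox17 and Creb3l1, transcription factors, were 34.5-fold and 18.0-fold above the placenta and the VYS, respectively. Birc7 was 230.1-fold above the placenta, Drp2, a dystrophin relative, 48.0-fold above the small intestine, and Tpbgl at least 33.0-fold. The largest adjusted p of these 14 genes was 5.49e-06.

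Of the 22 collagen folding genes above background in the PYS 11 were enriched there, among them P4ha1, P4ha2, Plod2 and Serpinh1 (Fisher adjusted p = 6.43e-10). So were 9 of 25 basement membrane genes (adjusted p = 7.49e-07), among them Lamb1, Lamc1, Nid1 and Nid2, and 7 of 20 parietal endoderm markers (adjusted p = 1.93e-05), among them Pth1r and Thbd. Endoderm transcription factors passed with 5 of 15 (adjusted p = 0.000565), namely Sox17, Gata6, Gata4, Tcf7l2 and Sox7, and immediate early genes with 4 of 24 (adjusted p = 0.0373), namely Klf4, Nr4a1, Atf3 and Egr2. The other 19 lists did not pass, among them trophoblast with 0 of 24.

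Both yolk sacs together were above each comparison organ for 53 genes, 47 of them named. Ctsh, a cathepsin, was 25.1-fold above the liver in the VYS and 14.5-fold in the PYS. Cgref1 was 12.4-fold and 44.0-fold above the liver. Timd2, a ferritin receptor, was 23.8-fold and 23.7-fold above the liver, Krt23, a keratin, 20.7-fold and 150.3-fold above the placenta, and Mogat1, an acylglycerol acyltransferase, 9.72-fold and 32.7-fold above the placenta. The largest adjusted p of these 5 genes was 8.31e-06.

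In the placenta 692 genes were enriched, 594 named. Ceacam13, a trophoblast cell surface gene, was 1045-fold above the PYS, Pappa2, a protease of IGF-binding proteins, 428-fold, and Ctsm, a placental cathepsin, 319-fold. Slco4a1, an organic anion transporter, and Irs3, an insulin receptor substrate, were 19.97-fold and 38.8-fold above the PYS. In the liver 339 genes were enriched, 274 named. Serpina6, the corticosteroid-binding globulin, was 2154-fold above the VYS, F12, a coagulation factor, 119.6-fold, Stfa3, a cysteine protease inhibitor, 130.2-fold, Car1, a red cell carbonic anhydrase, 34.5-fold, and Btnl10 at least 55.0-fold. The largest adjusted p of these 10 genes was 2.16e-05. With members below background at their bound, 336 VYS-enriched, 606 PYS-enriched, 569 placenta-enriched, 285 liver-enriched and 45 shared genes still reached a fold of at least 4 in every contrast.

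Against the placenta, the VYS had higher Spink1, a trypsin inhibitor, Afp and Serpina1a, an antitrypsin (2749.6-fold, 2118-fold and 1851-fold). Prl2c5, Prl8a2 and Prl3b1 were 4764-fold, 3971-fold and 3194-fold higher in the placenta. Of 37 trophoblast genes 34 were higher in the placenta and 0 in the VYS, and of 26 erythroid genes 1 was higher in the VYS, or 0 adjusted over the list alone. In all, 4562 genes were higher in the VYS and 3872 in the placenta (limma, adjusted p of the named genes at most 7.57e-06). Counting only features with a gene symbol, 2796 were higher in the VYS and 3054 in the placenta, so the side with more calls changed. These tissues shared no slide, and slide as a block gave 3360 and 2955.

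Against the liver, the VYS had higher Cubn and Lrp2, the endocytic receptors cubilin and megalin, and S100g, a calcium-binding protein of absorptive epithelia (1221-fold, 995-fold and 1083-fold). Serpina6, Cstdc5, a stefin-family inhibitor, and Camp, a neutrophil peptide, were 2154-fold, 507-fold and 196-fold higher in the liver. Plasma protein genes split evenly, 7 higher and 7 lower of 29 with a median of 0.052, while 25 of 30 endocytic genes were higher in the VYS and 21 of 26 erythroid genes in the liver, each count the same adjusted over the list alone. In all, 3570 genes were higher in the VYS and 4241 in the liver (adjusted p of the named genes at most 2.37e-05). Features with a gene symbol gave 2887 and 2814. Slide as a block, where the contrast rests on liver replicate 1, gave 3778 and 4951. In slide 1 alone, which holds 1 liver array, the median log2 difference of all genes was -0.26, against -0.25 in the main fit. The side with more calls depended on the setting, with more in the VYS by quantile scaling (3809 and 3171), normexp (2612 and 2519), the common floor (2926 and 2850), a fold of at least 4 (1725 and 1590) and the rule that the higher tissue be above background on all its arrays (3444 and 3362).

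Against the small intestine, a single array, the VYS had higher Fgb, Pdzk1, a scaffold of brush border transporters, and Apom (2154-fold, 997-fold and 751-fold). Synpo2, an actin-binding protein of muscle, Dpysl4, a neuronal protein, and Aldh1a1, a retinoic acid-forming enzyme, were 262-fold, 197-fold and 180.4-fold higher in the small intestine. Brush border genes were higher in the VYS in 19 of 30 and lower in 2, and intestinal muscle and enteric neuron genes were higher in the small intestine in 16 of 25, or 17 adjusted over the list alone. In all, 4404 genes were higher in the VYS and 5098 in the small intestine (adjusted p of the named genes at most 3.52e-04). Features with a gene symbol gave 3448 and 2790, with more calls in the VYS. Slide as a block gave 4677 and 5696, and slide 1 alone 4880 and 6064. More calls were in the VYS by quantile scaling (4684 and 4548), normexp (3579 and 3533), the common floor (3886 and 3606) and probes above background on all 11 arrays (3070 and 2103).

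Against the placenta, the PYS had higher Gkn2, Pga5 and Tbx22, a T-box transcription factor (6566-fold, 1281-fold and 1016-fold). Ceacam13, Ceacam5 and Prl4a1, trophoblast genes with close relatives, were 1045-fold, 676-fold and 600.5-fold higher in the placenta. Of 37 trophoblast genes 33 were higher in the placenta and 2 in the PYS, and of 27 collagen folding genes 18 were higher in the PYS and 3 lower, each count the same adjusted over the list alone. In all, 7669 genes were higher in the PYS and 4591 in the placenta (62.6% higher in the PYS, adjusted p of the named genes at most 2.84e-05), and 648 of the former had neither tissue above background. Counting only features with a gene symbol, 3461 were higher in the PYS and 3844 in the placenta, so the excess in the PYS lay in unnamed probes. Quantile scaling gave 5596 and 5754 (49.3%), slide as a block 7757 and 4487, and slide 2 alone 7504 and 4268.

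Against the liver, the PYS had higher Fabp3, a fatty acid-binding protein, Ccn2, a matricellular growth factor, and Pi16 (1661-fold, 936-fold and 736-fold). Fgb, Dlk1 and Serpina1d were 387-fold, 329-fold and 307-fold higher in the liver, where 27 of 29 plasma protein genes, 25 of 26 erythroid genes and 23 of 25 cell cycle genes were higher, also when adjusted over the list alone. In all, 7065 genes were higher in the PYS and 5602 in the liver (adjusted p of the named genes at most 3.41e-05). Features with a gene symbol gave 3982 and 4216, with more calls in the liver. Slide as a block, where the contrast rests on PYS replicate 1 and liver replicate 1, gave 6483 and 5278. In slide 1 alone, with 1 array of each, the median log2 difference of all genes was 0.14, against 0.055 in the main fit. More calls were in the liver by quantile scaling (6254 and 6482) and with probes above background on all 11 arrays (3107 and 3618).

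Against the small intestine array, the PYS had higher Prl2c5, Plbd1, a lysosomal phospholipase-like protein, and Edn2 (1701-fold, 874-fold and 639-fold). Aldh1a2, a retinoic acid-forming enzyme, Foxf1, a transcription factor of gut mesenchyme, and Hmga2, a chromatin protein, were 249-fold, 132-fold and 118-fold higher in the small intestine. All 30 of 30 ER chaperone genes were higher in the PYS, also when adjusted over the list alone, with a median of 1.81, against a median log2 difference of all genes of 0.27. In all, 5260 genes were higher in the PYS and 4137 in the small intestine (adjusted p of the named genes at most 1.23e-04). Features with a gene symbol gave 3657 and 3207. Slide as a block, where the contrast rests on PYS replicate 1 and the small intestine array, gave 5650 and 4200. In slide 1 alone, with 1 array of each, the median log2 difference of all genes was 0.28. By quantile scaling more calls were in the small intestine (4807 and 5114).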

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

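All settings below were planned except the common floor and the rule that the higher tissue be above background on all its arrays, which were chosen after seeing the data. Over 34 settings, 498 of 558 values of the 20 counts stayed within 1.5 times the count first reported and 60 moved further. Of 5442 values for the genes and lists named, 5386 kept their side of the threshold without a reversal, 47 lost their call, 7 gained one and 2 reversed. A change of direction counted as a reversal only where the result was called in at least 1 of the fits compared. Many of these genes were picked for a large fold or a small p in these data, which favours stability. Both reversals were Ermap, at 2.12 with normexp and 1.65 with the mean of its probes in place of -1.02. Its probes disagreed. F10 (VYS minus PYS, log2 difference) stood at -0.023 with the mean of its probes and lost its call. Normexp gave 2888 genes higher in the VYS than in the placenta, 2519 higher in the liver than in the VYS, and enriched sets of 244 (VYS), 295 (PYS), 424 (placenta), 181 (liver) and 26 (both yolk sacs), and the cause was not tested. With no filter on dim probes more features were tested, and 14167 genes were higher in the PYS than in the VYS and 13759 than in the placenta. The opposite calls hardly changed (4491 higher in the VYS and 4592 in the placenta), so the added calls fell on the PYS side. With the common floor (log2 -3.09) 4840 genes were higher in the PYS than in the VYS and 4842 than in the placenta. With that floor 2985 genes were higher in the VYS than in the placenta, since values under the floor no longer differ. With only probes above background on all 11 arrays, fewer features were tested. The counts were then 2580 and 2717 for VYS and PYS, 2243 and 1923 for VYS and placenta, 2020 and 2214 for VYS and liver, 2942 and 2632 for PYS and placenta, 3107 and 3618 for PYS and liver, and 3234 and 2384 for PYS and small intestine. In the small intestine 2103 genes were then higher than in the VYS. The enriched sets held 113, 215, 190, 93 and 21 genes, in the order above. Without the small intestine, which removes a contrast from the rule, 2136 genes were PYS-enriched, 516 liver-enriched and 116 shared by both yolk sacs. With no fold threshold 6746 genes were higher in the VYS than in the PYS and 6593 higher in the liver than in the VYS. A fold of at least 4, a stricter rule, gave 2172 and 4433 for VYS and PYS, 2169 and 2066 for VYS and placenta, 1725 and 1590 for VYS and liver, and 2209 and 3153 for VYS and small intestine. It gave 4855 and 2211 for PYS and placenta, 4361 and 2366 for PYS and liver, and 2641 and 2204 for PYS and small intestine. At fold 2 the enriched sets held 836, 1579, 1356, 774 and 175 genes, and at fold 8 they held 195, 282, 368, 159 and 19. An estimated correlation left 4 of 17 lists called. Leaving out each replicate in turn gave 4322 to 4618 genes higher in the VYS and 6923 to 7695 in the PYS, 374 to 388 VYS-enriched and 644 to 771 PYS-enriched genes, and 17 lists in every case, and moved no count past 1.5 times. Where this left a tissue with 1 array, that array was assumed to vary like the others. For samples of the same replicate number, r of deviations was -0.0019 to 0.035 between VYS and PYS, and over all pairs of tissues it ran from -0.0911 (VYS and liver replicate 1) to 0.154 (PYS and liver replicate 1). The replicate block gave 4490 and 7423 genes. Scan date split the arrays as the slides did and no probe was saturated, so those 2 alternatives were not run.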

Other observations

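The gene families, the common floor, the rule that the higher tissue be above background on all its arrays, and the tests of explanations other than the 2 counts of regroupings of the arrays were chosen after the results they bear on had been seen, while the other settings were planned. Solute carriers stood out among the VYS-enriched genes, with 24 of 326 named genes against 275 of 13970 named genes above background in the VYS (7.36% against 1.97%, one-sided Fisher's exact test, adjusted p = 1.47e-06 over 100 tests of 20 families in 5 sets). Slc22a6, an organic anion transporter, was 57.1-fold above the next highest tissue, Slc39a4, the intestinal zinc transporter, 25.9-fold, and Slc34a3, a phosphate transporter, was at least 138-fold above the PYS. Slc2a7 and Slc5a4b, also counted, had bounds under 4-fold, at least 1.85-fold and at least 3.88-fold above the PYS. Cytochromes P450 also passed (7 genes, adjusted p = 0.00107), among them Cyp21a1, the steroid 21-hydroxylase, 54.8-fold above the next highest tissue. So did genes with a Ugt symbol (4 genes, adjusted p = 0.00172), namely Ugt1a10, Ugt1a6b, Ugt3a2 and Ugt8a, the last at least 3.38-fold above the PYS. Claudins passed too (3 genes, adjusted p = 0.0433), with Cldn2 at least 151-fold above the PYS. Collagens passed with 7 genes (adjusted p = 0.00018), among them Col2a1 and Col9a2, chains known from cartilage, Col9a2 being 12.4-fold above the next highest tissue.

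Among the PYS-enriched genes 4 of 9 laminin chains stood out (adjusted p = 0.00172). Lama1, Lamb1 and Lamc1, the chains of laminin-111, were 11.97-fold, 14.7-fold and 16.3-fold above the next highest tissue, and Lamc2 4.68-fold. Keratins (5 of 20, adjusted p = 0.0047), namely Krt222, Krt23, Krt6a, Krt6b and Krt75, and Wnt ligands (3 of 8, adjusted p = 0.0157), namely Wnt6, Wnt7b and Wnt11, passed too. In the placenta 17 of 22 prolactin-family genes were enriched (adjusted p = 7.13e-18), with 8 of 18 cathepsins (adjusted p = 9.46e-06) and 8 of 29 serpins (adjusted p = 0.000369), families whose members are close copies and can share probes. Keratins in the placenta (5 of 22) and serpins in the liver (4 of 25) passed at an adjusted p of 0.0157 each. Of the placental members counted, Prl5a1, Serpina3n and Krt33b had bounds under 4-fold. They were at least 1.12-fold, at least 1.17-fold and at least 1.67-fold above the PYS.

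Trophoblast genes were higher in the PYS than in the VYS, 29 of 37, though in 7 of the 29 neither tissue was above background. The list lost its call with an estimated correlation (camera adjusted p = 0.181). Placental tissue carried over into the PYS samples would bring all its abundant transcripts at about the same share. Of the 20 most abundant placenta-enriched genes with a name, 19 were above background on all PYS arrays and 1 on 1 array, with a median log2 of -4.33 for PYS minus placenta, though several were also high in the VYS. The 8 above background on all PYS arrays and on no VYS array ran from -10.0 (Ceacam13) to -2.31 (Prl2a1), with an SE of at most 0.93. Spongiotrophoblast and labyrinth markers lay further below the placenta (median log2 -7.86 for PYS minus placenta, 16 genes) than giant cell markers (-2.47, 9 genes), a difference of -5.39 (two-sided permutation test with 100000 resamples, p = 0.0244). Of the 16, 6 were above background on no PYS array, and with these at their bound the median was -7.44 and the difference -4.98 (permutation test, p = 0.0287). These unequal shares argue against carry-over of whole placenta as the only cause. The permutation tests treat genes as independent, while several markers are close relatives, so their p-values may be too small. Among the 8 markers above background on all PYS arrays the difference was -4.34 (permutation test, p = 0.0906), but that subset is chosen by the PYS signal itself and includes Psg23 (0.48) and Slc16a3 (-1.04), which were at similar levels in the VYS. Trophoblast giant cells attached to Reichert's membrane stay open as a source. That 8 of the 9 giant cell markers were above background on all PYS arrays and called higher in the PYS than in the VYS does not decide it, since they are among the genes to be explained. Hand1 was the exception, and Prl4a1 reached only 0.167% of its placental level, while Gcm1, a labyrinth factor, was higher in the PYS than in the placenta by 4.25 on the log2 scale (adjusted p = 0.000126). Expression by the parietal endoderm itself was not tested and stays open, and several of these genes have near-identical relatives.

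More genes were called higher in the PYS than in the VYS, 62.5% of calls. Among named features 3823 were higher in the PYS and 3519 in the VYS, so most of the excess lay in unnamed probes. In 507 of the calls higher in the PYS, and in 0 of those higher in the VYS, neither tissue was above background on any array. With no filter on dim probes, calls higher in the PYS rose from 7477 to 14167, against 4494 and 4491 higher in the VYS. Background-level signals thus make up part of the excess. For the remaining calls, background-level signals raised by scaling the dimmer PYS arrays and a wider set of active genes in the PYS cannot be told apart here. Among probes above background on all 11 arrays the share was 51.3%, but that filter also removes genes active in the PYS alone. The share was 55.8% with the common floor, 55.0% when the higher tissue had to be above background on all its arrays, 48.5% with quantile scaling, 75.9% with no filter and 68.4% with normexp. Scaling to the median of probes above background on all arrays gave 65.3%, but this is 1 other scaling point, so the position of the 75th percentile stays open as a cause. The other 9 of the 10 splits of the 6 arrays gave 0 genes called by limma, with 181 to 365 genes at an unadjusted p under 0.05, against 11971 calls and 17510 genes for the real split. They gave 11 to 15 lists called by camera against 17. Each of these 9 splits mixes VYS and PYS arrays within a group. The tissue difference then widens the spread within groups, which by itself leaves little room for gene calls. For genes and for lists 1 split, the real one, gave as many, but 10 splits are too few for a share under 0.05.

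Mesenchymal, endothelial and erythroid genes were higher in the VYS than in the PYS (median log2 4.66, 2.67 and 3.25, or 3.53, 2.67 and 2.46 with bounds). With an estimated correlation the 3 lists lost their call (camera adjusted p = 0.288, 0.354 and 0.278). The medians of mesothelial and leukocyte genes were -0.22 and 0.42, and these 5 lists differed (permutation test of the Kruskal-Wallis statistic, p = 0.00018). That test treats genes as independent. Each difference also depends on how much of a cell type the PYS samples hold. Unequal lists therefore cannot decide whether a lower share of endoderm in the VYS samples is the cause. With slide as a block or within slide 1, which gave the same means, the lowest mean of the 3 lists was 2.75. Slide 1 holds 1 PYS array, so this comparison does not settle whether the slides contribute. The mesoderm layer and the blood vessels that belong to the VYS remain a possible explanation, which was not tested.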
